A study of Thermomyces lanuginosus with 4 samples.

How the data were processed

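RNA was measured in 4 libraries of mycelium of Thermomyces lanuginosus strain P134, a thermophilic filamentous fungus. The mycelium was 2 days old and had been cultured either on Avicel, a brand of microcrystalline cellulose, or on glucose. Each carbon source had 2 libraries, sequenced on an Illumina Genome Analyzer IIx per the series' design text. The labels do not say whether the 2 libraries of a group came from separate cultures. All limma p-values below therefore measure only the spread between these libraries, which may be technical. The p-values computed across genes or pairs of genes do not measure that spread.

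The authors deposited 1 table per library with a single FPKM value (fragments per kilobase of transcript per 1000000 mapped fragments) for each of 9704 gene IDs, per the file headers. The values are rounded to 2 decimals and the IDs are in the same order in all 4 tables. The submitters' processing notes name RSEM 1.2.15, a program that estimates transcript abundance, and Bowtie2, an aligner whose version is not given in the sources used here. The reference sequence, its annotation and any filter on the reads are not given in the sources used here. The IDs consist of a component number and a gene number (c8817_g1), the form that transcriptome assemblies made without a genome use, although no label states that one was made. None of the 9704 IDs occurs in the gene table of a RefSeq assembly of another strain, which lists 8214 genes. No gene name, function or position could therefore be attached to an ID, and the 30 functional gene lists fixed before the data were examined (cellulases, beta-glucosidases, sugar transporters, ribosomal proteins and others) could not be built or tested. FPKM values carry no counts, so the absolute depth is unknown and no counting interval is given.

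FPKM is relative to all fragments of a library, so a gene's value also moves when other genes take more or less of the total. No further scaling between libraries was applied in the main test. Genes with at least 1 FPKM in at least 2 libraries were tested, which left 8261 genes and set 1443 aside. Values were transformed as log2(FPKM + 1) and compared with limma 3.58.1 in R 4.3.3, using the empirical Bayes moderated test with an abundance trend, carbon source as the only term, 2 residual and 2.34 prior degrees of freedom, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The plan fixed beforehand held a count test as well, for the case that the files gave counts, which they do not.

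The fit was tested on simulated values, in which 200 of the genes were changed. Their spread was drawn around a smoothed spread of these libraries with added variation between genes, which made the variance larger on average. Among 7915 simulated genes that passed the filter, limma recovered 43.8% of the 1.5-fold, 63.5% of the 2-fold and 80.6% of the 4-fold changes. It made 122 calls, 4 of them on unchanged genes. In the data 62.6% of the tested genes were called, a far larger share than was changed in the simulation. These rates therefore need not hold for the fit to the data.

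The relative depth of the libraries was estimated from genes with very few reads. For such a gene the FPKM of 1 read is inversely proportional to library depth. The ratios between libraries therefore pile up at a depth step set by the depths, and at that step times ratios of small whole numbers. Genes above 0.4 FPKM in both libraries of a pair and listed at 0 in at least 1 other library were used. Between 30.9% and 42.3% of the ratios of a pair lay within 0.1 on the log2 scale of the depth step itself. With ratios of small whole numbers included, fractions among them, the range was 69.1% to 87.9%. The share that would fall there by chance was not worked out. On simulated data of 9704 genes the largest error of an estimated depth was 0.29%. The simulation drew whole read counts with counting error only, at a preset depth and with preset gene lengths. Each gene had the same mean in all libraries, without a difference between carbon sources. The real libraries do differ by carbon source, so this error need not hold for them. The 6 pairwise ratios of the real libraries fitted 1 set of depths to within 0.022 on the log2 scale. Each ratio was sought only within 0.1 of a jointly chosen set, so a close fit was partly built in and does not test the method.

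Because the files hold no names, the naming rule fixed beforehand gave the 2 genes that rose most and the 2 that fell most. They had to be called, to have both Avicel libraries on the same side of both glucose libraries, and to have a mean of at least 10 FPKM over the 4 libraries. The alternatives fixed before the data were examined were pseudocounts of 0.1 and 10, no filter, a filter of 10 FPKM, a replicate block, each library left out in turn and a test against a 1.5-fold change. Robust empirical Bayes, median-of-ratios scaling, rescaling to a total of 1000000 (TPM), quantile normalization and rescaling to the total outside the 100 most abundant genes were added after seeing the data, as were fits without 1 library that kept all tested genes and a ranking of genes by mean log2(FPKM + 1). Figures and descriptive values were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.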

Results

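Transcript abundance was compared between mycelium grown on Avicel and mycelium grown on glucose, with 2 libraries for each carbon source, to find the genes whose expression differs when the fungus is supplied with crystalline cellulose. Each library listed 9704 genes, with FPKM totals between 541446 and 556312. Relative to the first Avicel library, the estimated sequencing depth was 93.1% in the second Avicel library, 80.4% in the first glucose library and 99.1% in the second. At least 1 FPKM was recorded for 7886 and 7893 genes in the Avicel libraries and for 8080 and 8145 genes in the glucose libraries.

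The libraries separated by carbon source. Across all genes, log2(FPKM + 1) had a Pearson correlation of 0.982 between the Avicel libraries and 0.976 between the glucose libraries, against 0.930 to 0.934 between libraries of different carbon source. Genes are not independent replicates, so these correlations only describe the libraries. Among the 1196 genes with a mean of at least 100 FPKM, the median difference within a pair of libraries was 2.15% on Avicel and 4.41% on glucose. Between libraries of different carbon source it was 37.3% to 38.7%.

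Expression differed between the carbon sources in 5171 genes. Of 8261 genes tested, 1912 rose and 3259 fell on Avicel relative to glucose (limma, adjusted p below 0.05), which is 62.6% of those tested. Without the first or the second Avicel library, 43.5% and 43.7% of the same genes were called. Most of these changes were small. A total of 540 genes rose and 747 fell by at least 2-fold, 143 rose and 149 fell by at least 4-fold, and 20 rose and 14 fell by at least 16-fold. These fold counts depend on the pseudocount. With 0.1 in place of 1, 215 genes were higher and 259 lower by at least 4-fold, and 77 and 87 by at least 16-fold. With 10, 276 were higher and 281 lower by at least 2-fold, 58 and 58 by at least 4-fold, and 5 and 4 by at least 16-fold. On the deposited scale, both Avicel libraries lay above both glucose libraries for 30.7% of the tested genes and below both for 51.3%. A random order of the 4 libraries would give a single gene a 16.7% chance of each. All genes share the same libraries, and a difference in scale between them moves all genes together. These shares are therefore descriptive and not a test against chance. Called genes with 0 FPKM in both libraries of one carbon source numbered 131, with a median of 1.1 FPKM over the 4 libraries.

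The split between genes that rose and genes that fell depended on the scale on which the libraries were compared. On the deposited FPKM scale the median change of all tested genes was -0.16 (log2), and 63.0% of the called genes were lower on Avicel. After median-of-ratios scaling, which brings that median to -0.01, 2478 genes were called higher and 2357 lower, so that 48.7% of the calls were lower. Quantile normalization gave 2340 higher and 2531 lower. The excess of genes at least 2-fold lower turned round with both, to 701 higher against 544 lower and 669 higher against 561 lower. Without the second glucose library it was 577 higher against 568 lower, but the filter then removed genes near 0 on Avicel, and with all tested genes kept it was 560 higher against 668 lower.

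**Figure D1:**
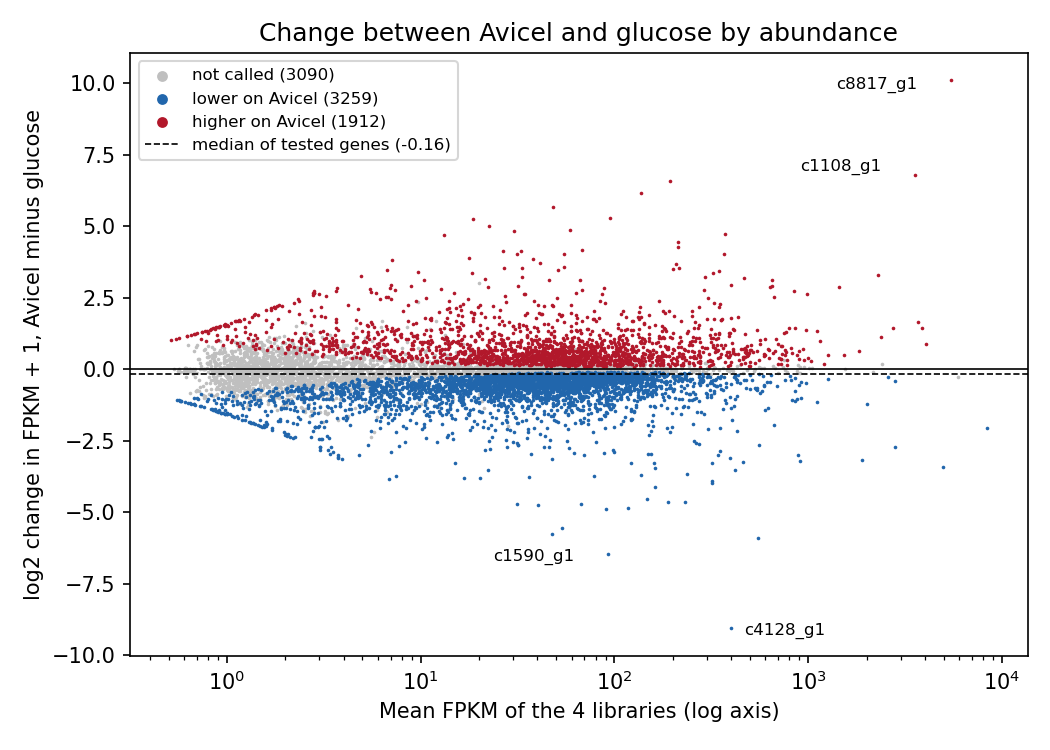
Each point is 1 of the 8261 tested genes, with its mean FPKM over the 4 libraries on a log axis and its log2 change in FPKM + 1 (Avicel minus glucose) on the vertical axis. Red points are the 1912 genes called higher on Avicel, blue points the 3259 called lower and grey points those not called; the dashed line is the median change of -0.16, and the straight edges at low abundance are genes listed at 0 on one carbon source.

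With a pseudocount of 1, the 2 genes with the largest increase were also the 2 most abundant on Avicel. A rise on the log2(FPKM + 1) scale is bounded by the Avicel value, so this ranking favours abundant genes and depends on the pseudocount. For example, 1 called gene had a mean of 37.19 FPKM on Avicel and 0 in both glucose libraries, so its ratio has no upper bound. The gene c8817_g1 had 10899 ± 276 FPKM on Avicel (SD, n = 2) and 8.995 ± 1.138 FPKM on glucose (SD, n = 2), a ratio of 1212. It ranked 1 by mean abundance on Avicel and 5494 on glucose, and by itself made up 1.97% of the summed FPKM on Avicel. Its log2 change was 10.10 ± 0.09 (SE; limma adjusted p = 7.39e-06). The gene c1108_g1 rose from 62.03 ± 1.697 FPKM on glucose to 7020 ± 123 FPKM on Avicel (SD, n = 2 each), a ratio of 113, and from rank 2168 to rank 2. Its log2 change was 6.80 ± 0.04 (SE; limma adjusted p = 7.39e-06).

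With a pseudocount of 1, the 2 genes with the largest decrease were close to the lowest values in the tables on Avicel. Their changes therefore depend on the pseudocount, and with 10 they were -6.25 for c4128_g1 and -4.12 for c1590_g1 (log2). The gene c4128_g1 had 803 ± 202 FPKM on glucose and 0.485 ± 0.007 FPKM on Avicel (SD, n = 2 each). It ranked 55 on glucose, and its log2 change was -9.06 ± 0.18 (SE; limma adjusted p = 2.24e-05). Its values in the glucose libraries, 945 and 660 FPKM, differed more than those of the other named genes. The gene c1590_g1 had 183 ± 2.83 FPKM on glucose and 1.08 ± 0.205 FPKM on Avicel (SD, n = 2 each), with a log2 change of -6.47 ± 0.09 (SE; limma adjusted p = 1.16e-05). The number of reads behind the Avicel values of both genes is unknown, so their ratios are uncertain.

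**Figure D2:**
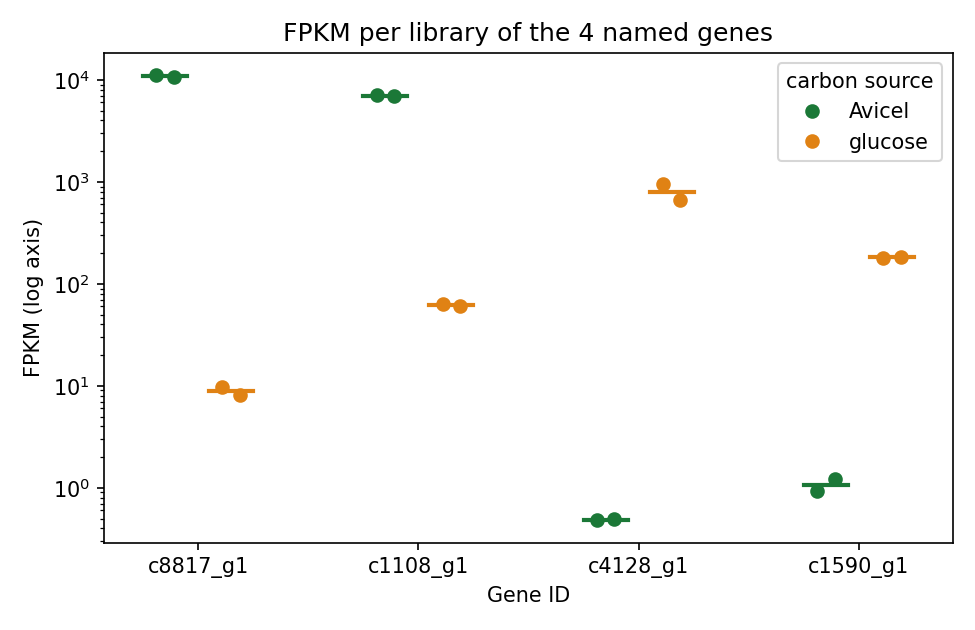
FPKM on a log axis for the 4 named genes, with 1 point per library and a bar at the mean of the 2 libraries of each carbon source (green, Avicel; orange, glucose). The genes c8817_g1 and c1108_g1 reach at least 6933 FPKM in both Avicel libraries, and c4128_g1 and c1590_g1 stay at or below 1.22 FPKM in both.

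The most highly expressed genes differed between the carbon sources. Of the 10 most abundant genes on Avicel and the 10 on glucose, 3 were shared, and of the 100 most abundant on each, 62 were shared. Replicate libraries shared 99 of their 100 most abundant genes on Avicel and 94 on glucose. Of the 62 shared genes, 30 were called higher on Avicel, 14 lower and 18 neither way. The most abundant gene on glucose had 13417 ± 964 FPKM there and 3263 ± 241 FPKM on Avicel (SD, n = 2 each), a log2 change of -2.04 ± 0.11 (SE; limma adjusted p = 2.22e-04), and still ranked 9 on Avicel.

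The 10 most abundant genes of a library took 9.85% ± 0.01 of the summed FPKM on Avicel and 9.33% ± 0.31 on glucose (SD, n = 2 each). The 100 most abundant took 26.8% ± 0.02 on Avicel and 24.3% ± 0.33 on glucose (SD, n = 2 each). With 2 libraries a group, no permutation test of these shares can pass 0.05, and none was run. The 1912 genes called higher made up 51.4% of the summed FPKM on Avicel and 27.1% on glucose, and the 3259 called lower made up 30.6% and 54.3%. Genes were put in these sets by the same values, so the direction of each difference was fixed in advance and only its size is descriptive. The same holds for the sets that follow. The 143 genes at least 4-fold higher made up 8.91% of the sum on Avicel and 0.75% on glucose, and the 149 at least 4-fold lower made up 1.47% on Avicel and 10.1% on glucose.

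Among genes grouped by abundance, those with a mean of 200 FPKM or more were on the deposited scale the one class in which more genes rose than fell. In that class 246 of 496 genes rose and 182 fell on Avicel. In the class from 50 to 200 FPKM, 662 of 2136 genes rose and 1072 fell. Of 2785 genes from 10 to 50 FPKM, 675 rose and 1382 fell, and of 2844 genes under 10 FPKM, 329 rose and 623 fell. After median-of-ratios scaling 286 genes rose and 139 fell in the class of 200 FPKM or more, and from 50 to 200 FPKM 873 rose and 737 fell. The FPKM totals of the libraries are nearly equal, so a majority of genes that fell goes together with abundant genes that rose, and these counts are not independent evidence of a direction. A change of at least 4-fold was found in 54 genes (10.9%) of the class of 200 FPKM or more and in 148 of 4921 genes (3.01%) between 10 and 200 FPKM. A mean over 4 libraries is itself raised by a high value on either carbon source. With genes ranked by their mean log2(FPKM + 1), which lowers that dependence, 36 of the 496 highest genes (7.26%) changed at least 4-fold, against 148 of 4862 others above 10 FPKM (3.04%; Fisher's exact test across genes, two-sided, p = 1.18e-05). Genes are not independent replicates, so this p-value is too small.

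**Figure D3:**
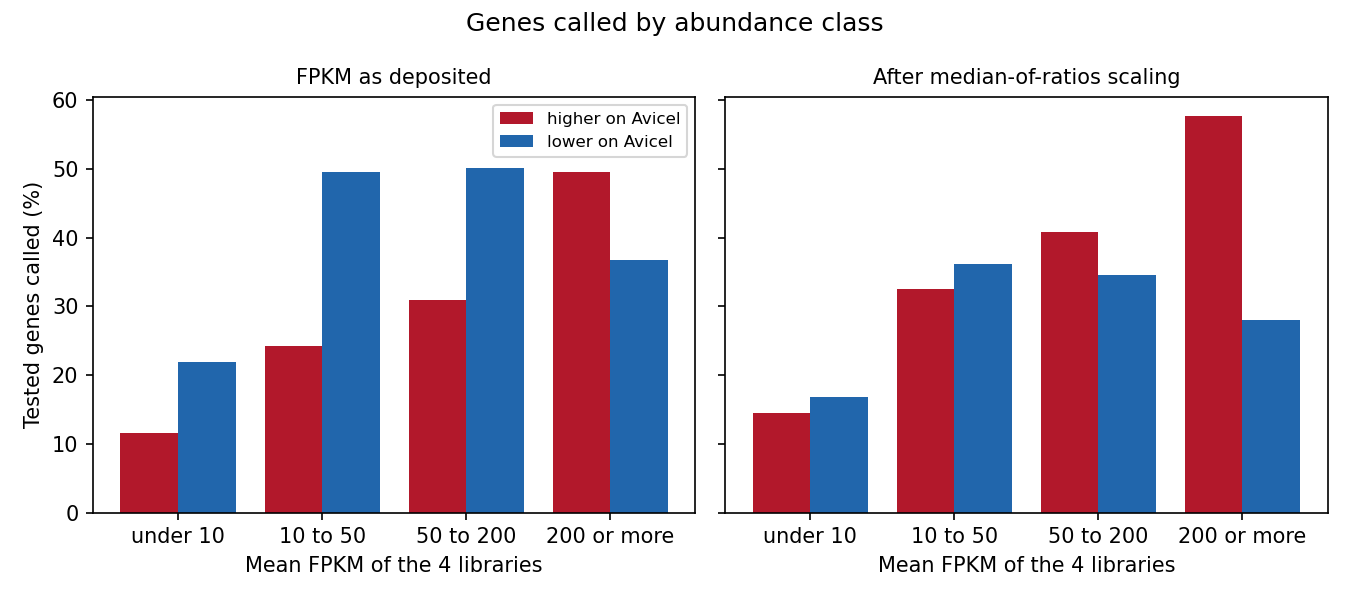
Percent of tested genes called higher (red) or lower (blue) on Avicel, in 4 classes of mean FPKM, on the deposited scale (left) and after median-of-ratios scaling (right). In the class of 200 FPKM or more the red bar is the taller one in both panels, with 246 genes higher and 182 lower on the deposited scale.

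For 2946 of the 8261 tested genes (35.7%), the 95% interval of the change in FPKM + 1 lay within 1.5-fold in either direction, and 1660 of these were nonetheless called. For genes with low values this scale still allows a larger change in FPKM, and the interval covers only the spread between these libraries. After median-of-ratios scaling, 3111 genes had such an interval within 1.5-fold. A change beyond 1.5-fold was called for 1421 genes (17.2%; limma test against that bound), 607 higher and 814 lower.

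Few genes reached 1 FPKM in both libraries of one carbon source while listed at 0 in both of the other. A total of 58 genes had at least 1 FPKM in both Avicel libraries and were listed at 0 in both glucose libraries, and 73 showed the opposite. Their median level where recorded was 2.06 and 2.29 FPKM, and 1 gene in each set reached 10 FPKM. The same criterion applied to the other 2 ways of splitting the 4 libraries into pairs gave 40 and 39 genes, and 43 and 40 genes. All 131 genes of the split by carbon source were called by limma. Their selection, 0 in both libraries of one group and at least 1 FPKM in both of the other, nearly fixes that outcome. The calls therefore add no support, and the number of reads behind these genes is unknown.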

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

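Robust empirical Bayes, the scalings and the fits that keep the tested genes were added after seeing the data. Of the 5171 called genes, 4269 stayed called with median-of-ratios scaling and 4383 with quantile normalization. None that was also called under an alternative run had the opposite direction there, but this check leaves out genes that lost their call. The total number of calls was 5102 and 5158 with pseudocounts of 0.1 and 10, 5058 without a filter, 4497 at 10 FPKM or more, 5140 with robust empirical Bayes, 4835 with median-of-ratios scaling, 4871 with quantile normalization and 5158 as TPM. Leaving out 1 library gave 4125 to 4787 calls, and 3590 to 4450 when the 8261 tested genes were kept; in these fits 1 carbon source has a single library, which is assumed to vary like the pair of the other. Testing against 1.5-fold left 1421 genes, 607 higher and 814 lower, since it asks for a larger change. The labels do not say that equal replicate numbers share a culture or day, and deviations of same-numbered libraries had a correlation of -0.001 over tested genes and of 0.272 over the 1196 genes with a mean of at least 100 FPKM. With the replicate as a block 5029 genes were called, 4884 of them shared with the unblocked fit. Genes at least 2-fold higher and lower, 540 and 747, became 276 and 281 with a pseudocount of 10, and the filter of 10 FPKM gave 497 lower. Genes at least 4-fold changed, 143 and 149, became 215 and 259 with a pseudocount of 0.1 and 58 and 58 with 10, and those at least 16-fold changed, 20 and 14, became 77 and 87, and 5 and 4. The 4 named genes were called in every alternative that tested them; c4128_g1 fell below the filter when either glucose library was left out and the filter reapplied. Without each library's most abundant gene, the 10 next took 8.51% on Avicel and 7.46% on glucose, and the 100 next 25.5% and 22.5%. Tests on counts, gene lists and ribosomal or mitochondrial genes were not run, for lack of counts and names. The share of genes called was smallest among the lowest genes: 33.5% of genes under 10 FPKM were called, against 86.3% at 200 FPKM or more. The part of the unknown depth in this was not tested.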

Other observations

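The test on depth was chosen after the result was seen. More genes were listed at 0 in both Avicel libraries, 482, than in both glucose libraries, 368, and 374 genes were at 0 only on Avicel against 260 only on glucose (exact McNemar test across genes, two-sided, p = 6.82e-06). Genes are not independent replicates, so this p-value is too small. Single libraries listed 846 and 880 genes at 0 on Avicel and 799 and 702 on glucose, so the glucose libraries also differed from each other. Deeper sequencing of the glucose libraries would require them to hold more reads. The depth estimated from 1-read steps argues against that, since the glucose libraries together had 0.929 times the depth of the Avicel libraries. Multiplying each library's depth by its median-of-ratios factor turned the ratio into 1.052. That factor takes the typical gene as unchanged between the carbon sources, which these relative values cannot show. A small difference in effective depth therefore stays open. A wider set of weakly expressed genes on glucose, the biological alternative that the design offers, was not tested separately.

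The excess of genes that fell on Avicel might be expected if a few abundant genes, such as c8817_g1, took a larger part of the reads and pushed all other FPKM values down. Rescaling each library to its total outside the 100 most abundant genes moved the median change from -0.16 to -0.109 (between -0.115 and -0.106 over the 4 pairs of libraries) and the share of lower calls from 63.0% to 58.6%. The 100 most abundant genes therefore do not account for the whole shift. Median-of-ratios scaling removes the shift by construction and decides nothing. Whether most genes fell in absolute amount, or a broader group of abundant genes rose, stays open, because relative abundances without an added standard hold no absolute scale.

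Genes whose IDs share a component number changed more alike than random pairs, with a wide scatter. Over 326 such pairs among the tested genes, the median absolute difference of the log2 changes was 0.476, against 0.728 for random partners of similar abundance (95% of 10000 draws between 0.646 and 0.819; permutation p = 0.0001, the smallest these draws can give), a ratio of 0.65. The correlation of the log2 changes within pairs, across genes, was 0.32, above the upper end of the central 95% of the draws, 0.13. Where both members were called, 101 of 128 pairs (78.9%) had the same direction, against 54.3% for random partners (95% of draws between 45.7% and 62.8%). The 326 pairs held 511 genes, so some pairs shared a member. The draws took partners for each pair independently, so these intervals may be too narrow and the p-value too small. The bounds set before this test were a ratio below 0.5 for reads of one gene split over several IDs, and 0.8 or more against that. They were chosen and not derived from data. The value lies between these bounds, so the test gave no answer. Related genes that respond alike could lower the ratio as well, so it cannot tell them from split reads without the sequences. Counts of genes are therefore counts of IDs, 9704 in all, which fall into 9390 components.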
